A study of Mus musculus with 3 samples.

How the data were processed

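Total RNA from the utero-tubular junction of adult CD-1 females in estrus was hybridised to Agilent single-colour mouse arrays labelled with Cy3, per the labels. The 3 arrays each held 1 pool of 10 females: not mated, mated with a vasectomized male, or mated with a normal male. Groups were taken from the mating labels. The time between mating and tissue collection is not given in the sources used here.

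The deposited intensity values are the processed signals of Agilent Feature Extraction, in linear units, corrected within each array for background and spatial trends and not scaled between arrays, per the file headers. The submitters' processing notes name version 9.5.3 of that software and the file headers name version 10.5.1.1. All 3 arrays carry the same slide scan in their headers. Each array has 45018 spots, of which 43379 are not controls, for 41174 probes, and 245 probes are printed 10 times. The mean log2 value over the spots of a probe was used. The number of arrays, 1 per group, limits the precision, and no p-value or standard error is given. No paired comparison, leave-one-out or permutation of labels was possible.

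The log2 values were computed here from the deposited intensities as log2 of the processed signal minus the 75th percentile of the array over non-control probes. Normalization used R 4.3.3 with data.table (version 1.17.8) and limma (version 3.58.1). Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Spots with the software's outlier flags were left out, and no spot was saturated. Probes were matched to gene symbols through the RefSeq gene table of the mouse assembly GRCm38.p6: 23082 probes by accession, 6582 by current symbol and 3073 by synonym, while 8437 kept the name given in the files, for 27666 distinct names. No genome build is stated for the arrays, so no coordinates are given. The value of a gene is that of its probe with the highest mean signal over the 3 arrays, with probes well above background on at least 1 array preferred. Where its other probes differ in sign or by over 2-fold, their range is given. A ratio with only 1 of its 2 arrays well above background is a bound, and genes with neither were not compared. Genes count as different at 2-fold. The median SD of log2 signal between the replicate spots of a probe was 0.0573 on the not mated array (189 probes well above background), 0.0644 on the vasectomized-mated array (189 probes) and 0.0541 on the normal-mated array (195 probes), which covers hybridisation and scanning and not animals.

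The comparisons, the thresholds, the gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. Named genes are, per comparison and direction, the 10 with the largest log2 ratio among genes well above background on both arrays, without outlier flags, with an official-style symbol, and at least 2-fold the same way with the main scaling, normexp background correction and quantile normalization. To these were added the 5 largest bounds per direction, up to 4 members of each list with the largest absolute ratio, Ovgp1 and the reference genes. Some genes that the rule names are not reported here. The 36 lists hold 681 distinct genes, of which 666 were on the array, 2 of them through a synonym. They cover inflammatory cytokines and chemokines, the NF-kB pathway, neutrophils, macrophages, T and NK cells, B and plasma cells, antigen presentation, mast cells and eosinophils, interferon-stimulated genes, immediate early genes, heat shock, complement, secreted defence, prostaglandins, matrix proteases, stroma, smooth muscle, endothelium, ciliated and oviduct secretory epithelium, uterine epithelium, oestrogen and progesterone responses, cell cycle, junctions, ion transport, steroid receptors and enzymes, growth factors, hypoxia, sperm, seminal vesicle, ovary, adipocytes, red blood cells, skeletal muscle and nerve, and reference genes. Some genes are in more than 1 list, such as Car9, Muc1 and Hsd3b1. Each list median was set beside 10000 random lists of the same size matched on expression in 20 bins, and its percentile describes these arrays only, since genes are not replicates.

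The counting and list steps were tested on simulated data with the levels of the not mated array and the replicate-spot noise, for normal mated versus not mated over 17206 genes. All 100 genes simulated at 3-fold passed 2-fold, 1 of 100 genes simulated at 1.5-fold did, and 0 unchanged genes did. The replicate-spot noise leaves out differences between probes and animals. This outcome was therefore nearly fixed in advance and does not give the false calls among measured genes. A simulated list shifted by 0.5 on the log2 scale reached percentile 100, and 10 of 200 unmoved lists lay outside the central 95%. The correlation of both matings across genes was set beside unchanged arrays simulated with the replicate-spot noise and sharing the not mated array. That noise is far smaller than the spread of the measured ratios, so the simulated covariance and overlaps are a lower limit.

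The alternatives were quantile normalization, the median of probes well above background on all arrays, cyclic loess, normexp background correction with an offset of 50, only genes well above background on both arrays, no filter on dim probes, outlier-flagged spots kept, the median over the probes of a gene, thresholds of 1.5-fold and 3-fold, lists without genes held by another list, and random lists not matched on expression. Scaling to the E1A spike-in probes, the 3'-most probe of each gene, and a comparison of the not mated and normal-mated arrays without the vasectomized-mated array were chosen after the data were seen.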

Results

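Gene expression was measured in the utero-tubular junction of adult CD-1 mice, the narrow passage between uterus and oviduct that sperm must cross to reach the egg. All females were in estrus. Each of 3 groups was represented by 1 pool of total RNA from 10 females, hybridised to 1 single-colour Agilent array: females that had not mated, females mated with vasectomized males and females mated with normal males. Mating with a vasectomized male delivers seminal fluid without sperm, so the series asks what mating alters at this site and what the presence of sperm adds. There was 1 array per group and no replicate, so the values below compare 3 pools and have no error between animals or arrays. Ratios are log2 values, and "at least" marks genes that were not well above background on the dimmer array.

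Of 43379 spots that were not controls, 68.0% were well above background on the not mated array, 65.9% on the vasectomized-mated array and 70.7% on the normal-mated array, and none was saturated. The vasectomized-mated array was the dimmest, with a 75th percentile signal of 295 against 874 on the not mated and 708 on the normal-mated array. Among genes with several probes, the probes lay over 2-fold apart for 51.9% of genes when the vasectomized-mated array was compared with the not mated one. The same share was 11.9% for the normal-mated against the not mated array. Across genes, r between the first 2 probes of a gene was 0.44 in the first comparison and 0.75 in the second, so single-gene values are less certain where the vasectomized-mated array is involved.

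**Figure D1:**
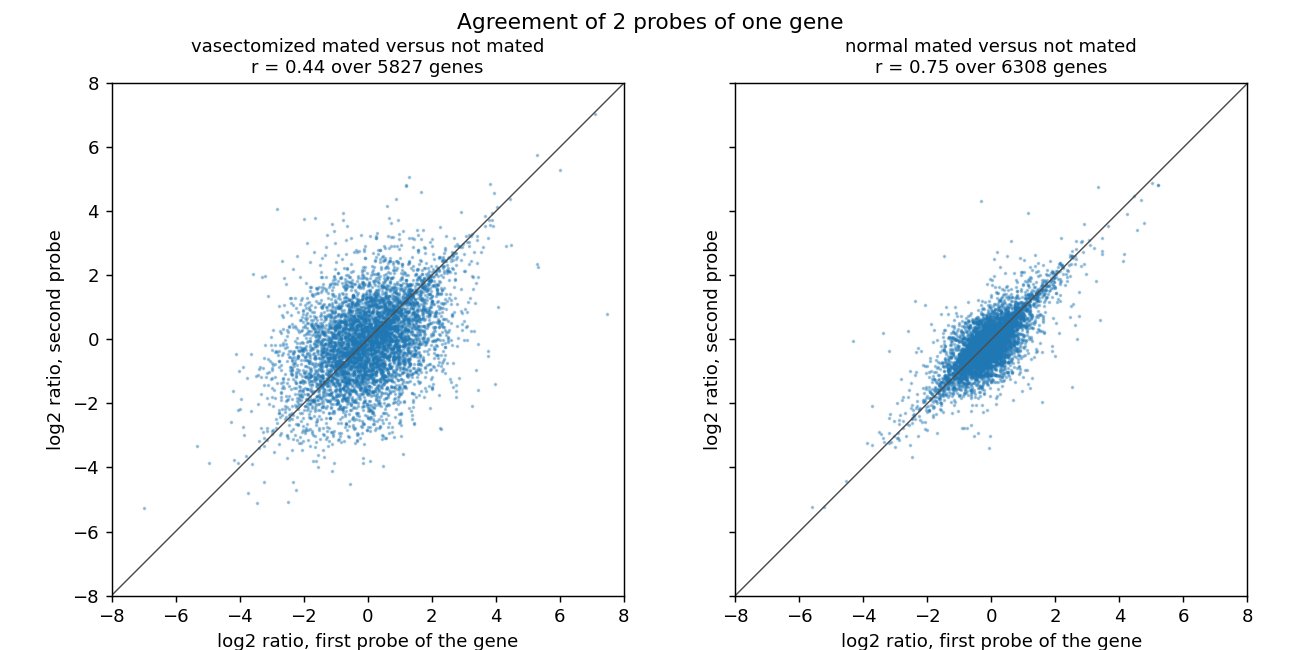
Log2 ratio of the first probe (horizontal axis) and of the second probe (vertical axis) of each gene with several probes well above background, 1 point per gene, for vasectomized mated versus not mated (left, 5827 genes) and normal mated versus not mated (right, 6308 genes). The points lie closer to the diagonal on the right, where r was 0.75, than on the left, where r was 0.44.

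After mating with normal males, genes of the innate inflammatory response were much higher than in females that had not mated. S100a9, a subunit of the neutrophil protein calprotectin, was 497-fold higher (log2 ratio 8.96), and its partner S100a8 was at least 208-fold higher. The neutrophil-attracting chemokines Cxcl5 and Cxcl1 were 275-fold and 54.7-fold higher, and the cytokines Il1b and Tnf 38.6-fold and 25.0-fold. Of 21 measured inflammatory cytokines and chemokines, 15 were at least 2-fold higher, 0 were at least 2-fold lower and 6 lay within 2-fold. Their median log2 ratio was 2.44, at percentile 100 of 10000 random lists matched on expression. Of 17 neutrophil markers, 14 were at least 2-fold higher and none lower, with a median of 2.57 (percentile 100). They included Mmp8, a neutrophil collagenase (3.47), and Csf3r, the receptor for granulocyte colony-stimulating factor (2.96).

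Interferon-stimulated genes were also higher after normal mating. Of 24 measured, 22 were at least 2-fold higher and 2 lay within 2-fold, with a median of 2.59 (percentile 100). Examples were Oasl1 (5.12), Oas3 (4.55), Ifi44 (4.10) and the ubiquitin-like Isg15 (3.75). Among the probes of Ifi44 the ratio ran from 2.46 to 4.10, and among those of Oas3 from 3.43 to 4.55. Of 22 genes for antimicrobial peptides and secreted defence proteins, 14 were at least 2-fold higher and none lower (median 1.89, percentile 100). Lcn2, which binds bacterial siderophores, was 76.1-fold higher. The acute-phase protein Saa3 was 50.3-fold higher, the membrane mucin Muc4 was 36.9-fold higher and Pglyrp1, which binds peptidoglycan, had a log2 ratio of 3.70. The NF-kB and toll-like receptor list had 11 of 23 genes at least 2-fold higher and none lower (median 0.86, percentile 100). It was led by Tnfaip3, a feedback inhibitor of the pathway (3.46), the lipopolysaccharide co-receptor Cd14 (2.60), Nfkbiz (2.49) and Birc3 (1.78). Of 18 complement genes, 7 were at least 2-fold higher and 2 lower (median 0.68, percentile 99.97), with factor B, Cfb, at 5.09 and Cfi at 2.61.

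The largest ratio after normal mating among genes well above background on both arrays was that of Sprr2d, a small proline-rich protein of epithelia, which was 2733-fold higher (11.42). Chil1, a chitinase-like secreted protein, was 782-fold higher, the secreted phospholipase Pla2g2e 268-fold, and Kap, a gene first described in kidney, 203-fold. Hsd17b2, which oxidises estradiol to estrone, was 90.2-fold higher, and Dmbt1, a secreted scavenger receptor, 89.4-fold. The largest bounds were those of Trim15 (at least 371-fold), S100a8, the interleukin 36 family cytokine Il1f9 (at least 57.4-fold), the keratin Krt25 (at least 48.6-fold) and the cystatin family gene Cstdc6 (at least 44.4-fold). Of 22 genes of ciliated epithelium, 15 were at least 2-fold higher and 2 lower (median 1.32, percentile 100), among them Ccno, needed for making many cilia (2.36), and Dnali1 (2.25). The oviduct secretory list had 8 of 15 genes higher and 1 lower (median 1.01, percentile 99.99), with Muc1 at 2.81, Cldn4 at 2.28 and Epcam at 1.66. Ovgp1, the oviductal glycoprotein, was within 2-fold of the not mated array after normal mating (0.26), with probes from -0.31 to 0.26. Uterine epithelial genes went both ways, 8 of 18 higher and 4 lower (median 0.72, percentile 99.99). Sprr2b (5.49) and Sprr2f (5.45) were higher, like Sprr2d, and Ihh, a hedgehog ligand of the uterine epithelium, was lower (-3.74). Cross-hybridisation between similar genes, such as those of the Sprr2 family, was not tested.

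Hypoxia and glycolysis genes were higher in 13 of 16 cases and lower in none (median 1.61, percentile 100). Egln3, a prolyl hydroxylase that acts on HIF proteins, was 90.4-fold higher, the carbonic anhydrase Car9 21.2-fold, Ankrd37 9.30-fold and the hexokinase Hk2 8.76-fold. Genes of ion, water and bicarbonate transport went both ways (median -0.05, percentile 33.5). The anion transporters Slc26a4 (4.77) and Slc26a9 (4.16) were higher and the water channel Aqp8 was lower (-3.70). Epithelial junction genes were at least 2-fold higher in 8 of 22 cases and lower in 2 (median 0.48, percentile 99.77), with the desmosomal Pkp1 at 2.58.

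Genes responsive to progesterone formed one of the lowest lists after normal mating. Of 20 measured, 13 were at least 2-fold lower and 1 higher, with a median of -1.72 (percentile 0). Cyp26a1, which degrades retinoic acid, was 15.3-fold lower, the endocytic receptor Lrp2 15.3-fold, Ihh 13.3-fold and the homeobox gene Hoxa11 11.5-fold. The largest negative ratio belonged to Prss28, a serine protease of uterine glands, which was 614-fold lower (-9.26), and its neighbour in function Prss29 was 23.4-fold lower. Other genes far lower were the kinesin Kif12 (-6.38), the dopamine receptor Drd4 (-6.26), the potassium channel subunit Kcne2 (-5.81), the transporters Abcb1b (-5.61) and Abcb4 (-4.58), Pinlyp (-5.24), Dio3, which inactivates thyroid hormone (-4.98), and Hsd11b2, which inactivates glucocorticoids (-4.65). Lower by at least 85.8-fold was the chloride channel Ano2, followed by Atp6v0d2 (at least 53.1-fold), Il13ra2 (at least 49.2-fold), the carbonic anhydrase Car4 (at least 48.4-fold) and Slc51a (at least 32.5-fold). Prostaglandin pathway genes had a median of -0.76 (percentile 0), with 9 of 26 lower and 4 higher. Ptgs2, the inducible cyclooxygenase, was 21.9-fold higher, whereas the phospholipase Pla2g10 was at -4.01. In the growth factor list 7 genes were higher and 8 lower of 24 (median -0.47, percentile 1.32), with Igfbp3 at -3.19 and Fgf10 at -2.71.

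Lists of stroma, smooth muscle, endothelium, and T and NK cells had medians below 0 after normal mating. Of 16 endothelial markers, 12 were at least 2-fold lower and none higher (median -1.48, percentile 0), among them Pecam1 (-2.23), Tie1 (-1.98) and Vwf (-1.89). Of 19 stromal and matrix genes, 11 were lower and none higher (median -1.20, percentile 0), led by Hoxa11, Hoxa10 (-2.89), Pdgfra (-1.94) and Col5a1 (-1.63). Smooth muscle genes had a median of -0.90 (percentile 0), with 7 of 18 lower and none higher, and Myh11, smooth muscle myosin, at -1.89. T and NK cell markers had the lowest median of all lists, -1.90 (percentile 0), with 9 of 14 lower, among them Gzmb (-3.46), Nkg7 (-3.08) and Prf1 (-2.65), which carry out cytotoxic killing. Mast cell and eosinophil genes were lower in 5 of 10 cases (median -0.95, percentile 0.90), with the mast cell proteases Mcpt4 (-3.02) and Cma1 (-2.63). Macrophage markers stood at a median of -0.11 (percentile 45.4), with the lysosomal Cd68 at 2.94 and the chemokine receptor Cx3cr1 at -1.54. Antigen presentation genes stood at -0.14 (percentile 44.2), a sign that differed with quantile, cyclic loess and normexp processing, and B and plasma cell markers at 0.38 (percentile 94.7). The co-stimulatory receptor Cd40 was at 2.55, whereas the class II genes H2-Aa and H2-Eb1 were at -1.94 and -1.77.

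No cell cycle gene of 25 differed by 2-fold (median -0.09, percentile 45.0). Heat shock genes lay within 2-fold for 14 of 15 genes (median -0.13, percentile 1.71), the exception being Hspb1 (-1.34). Immediate early genes stood at 0.24 (percentile 90.3), with Fos at 1.74, and proteases of the matrix and their inhibitors at 0.28 (percentile 96.0), with Plaur, the urokinase receptor, at 2.60. Oestrogen-responsive genes were higher in 9 of 24 cases and lower in 4 (median 0.30, percentile 94.8), with Cdkn1a at 2.82. Steroid receptors and enzymes had a median of -0.46 (percentile 2.79), with Srd5a1, a steroid reductase, at -2.67. Transcripts of sperm and testis lay within 2-fold for 12 of 13 genes (median 0.17, percentile 92.4). The seminal vesicle and prostate list, with 5 measured genes, had a median of 1.11 (percentile 99.3) that was -0.34 with only genes well above background on both arrays and -0.69 without a filter on dim probes. Ovary and cumulus transcripts stood at 0.15 (percentile 92.1), adipocyte markers at -0.17 (percentile 25.6), red blood cell transcripts at 0.38 (percentile 84.2) and skeletal muscle and nerve transcripts at 0.08 (percentile 77.3). Reference genes had a median of 0.32 (percentile 82.4), with the glycolytic Pgk1 at 2.15 and Gapdh at 1.53.

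In total, 1893 genes were at least 2-fold higher and 2545 at least 2-fold lower after normal mating among 19300 compared, so 42.7% of those past 2-fold were higher. That share was 52.9% with cyclic loess scaling (2199 higher, 1958 lower) and 59.4% with normexp background correction (1367 higher, 933 lower). Scaling to the spike-in probes, chosen after the data were seen, gave 1033 higher and 5517 lower. Among genes with several probes, 275 had every probe at least 2-fold higher and 319 every probe at least 2-fold lower.

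**Figure D2:**
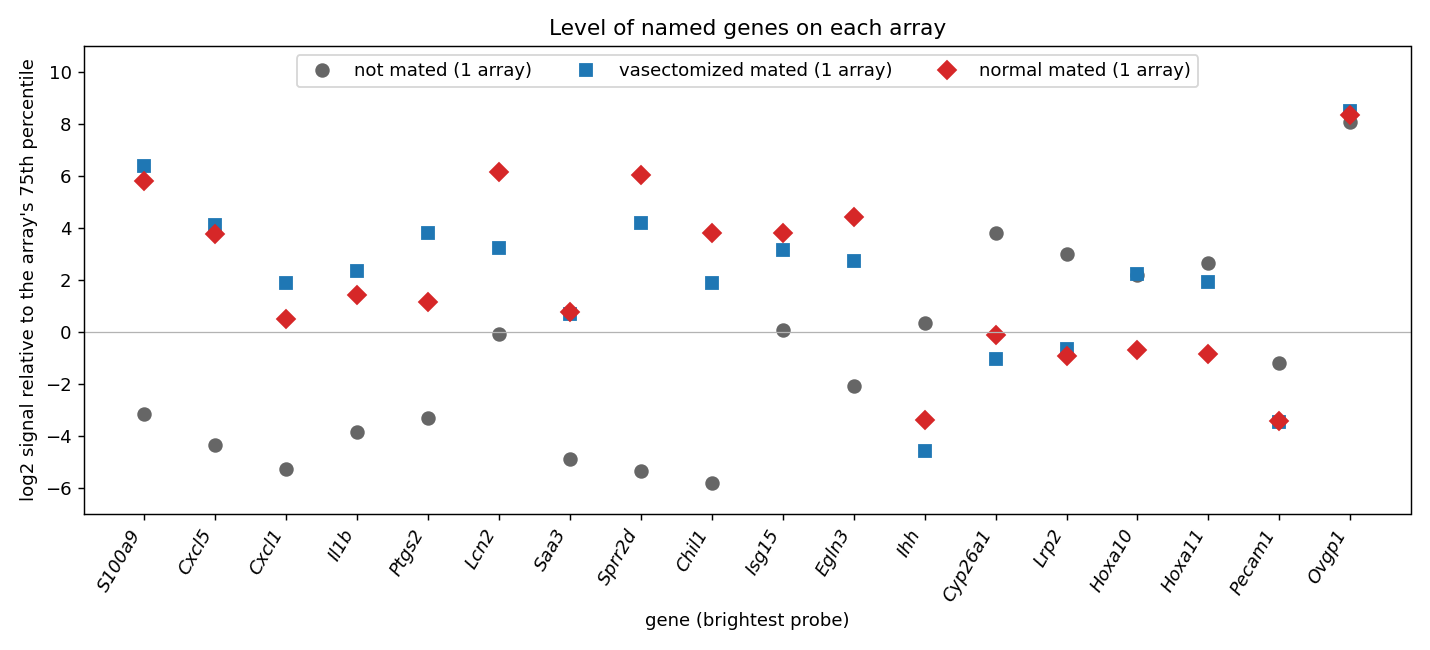
Log2 signal of named genes relative to the 75th percentile of each array (vertical axis) on the not mated (circles), vasectomized-mated (squares) and normal-mated (diamonds) array, 1 point per array with no error, for genes chosen among the named ones after their values were seen. S100a9 stood at -3.16 on the not mated array and at 5.80 on the normal-mated array, and Ihh at 0.33 and -3.41.

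After mating with vasectomized males the inflammatory genes were high as well. S100a9 was 742-fold higher than in females that had not mated (9.54), S100a8 at least 168-fold, Cxcl5 354-fold and Cxcl1 142-fold. The cytokine Il6 was 91.7-fold higher, Il1b 71.9-fold and Ptgs2 138-fold. Of 21 cytokines and chemokines, 17 were at least 2-fold higher and 1 lower (median 3.61, percentile 100). Neutrophil markers were higher in 15 of 16 cases (median 2.48, percentile 100), with the granule enzyme Mpo at 3.69. Macrophage markers were higher in 10 of 16 cases and lower in 1 (median 1.46, percentile 99.98), with Adgre1, the F4/80 antigen, at 3.73 and Mrc1 at 2.71. Interferon-stimulated genes were higher in 20 of 24 cases (median 1.92, percentile 100), led by Mx2 (4.01) and Ifi44 (3.38, probes from 1.76 to 3.38). Secreted defence genes were higher in 14 of 21 (median 2.35, percentile 100), with Saa3 at 5.59, the defensin Defb14 at 4.92 and Muc4 at 6.01, though the probes of Muc4 ran from 1.26 to 6.01. NF-kB genes had a median of 1.78 (percentile 100) with 13 of 23 higher, 2 lower and Tnfaip3 at 5.31. Complement stood at 1.18 (percentile 99.2), with Cfb at 4.24. Matrix proteases and their inhibitors stood at 0.92 (percentile 98.2), with Timp1, an inhibitor of metalloproteases, at 3.73 (probes from 2.41 to 3.73).

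The hypoxia list was higher in 10 of 16 genes and lower in 2 (median 1.48, percentile 99.80), with Egln3 at 4.83 and Ankrd37 at 4.29. Sprr2d was 751-fold higher, Chil1 209-fold, Kap 229-fold and the sodium bicarbonate cotransporter Slc4a7 134-fold. The largest ratio among the named genes was that of Mela (9.89), for which cross-hybridisation was not tested either. The steroid enzyme Hsd3b1 was 277-fold higher and Cyp11a1, which cleaves the cholesterol side chain, at least 147-fold, whereas the list of steroid receptors and enzymes had 3 of 14 genes higher and 4 lower, with Srd5a1 at -2.85. Other large bounds were those of Mgarp (at least 263-fold), Trim15 (at least 189-fold) and the oocyte-secreted protein gene Oosp1 (at least 64.3-fold). Of 14 ovary and cumulus transcripts, 8 were at least 2-fold higher and 1 lower (median 1.45, percentile 99.93), with the oocyte factor Gdf9 at 3.64 and Inha at 2.47. Ciliated genes were higher in 12 of 23 cases and lower in 2 (median 1.01, percentile 98.9), with Ccdc39 at 3.61. Of the 5 measured seminal vesicle and prostate transcripts 3 were higher and 1 lower (median 1.91, percentile 99.2), with Sbp at 3.42 here and at 3.99 after normal mating.

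Lower after vasectomized mating were Prss28 (at least 2833-fold), Prss29 (66.1-fold), Pinlyp (59.9-fold), the protease inhibitor Mug1 (48.6-fold), Bpifb5 (44.1-fold), the carboxylesterase Ces2b (38.5-fold), Jakmip1 (33.6-fold), Kif12 (32.6-fold), Ihh (30.7-fold, log2 ratio of its probes from -4.94 to -3.86), Efhd1 (29.4-fold) and Cyp26a1 (28.9-fold). The probes of Ces2b ran from -6.98 to -5.27 on the log2 scale and those of Jakmip1 from -5.07 to -2.48. Drd4, Ano2, Atp6v0d2 and Car4 were lower by at least 54.0-fold, 40.5-fold, 25.1-fold and 22.8-fold. Progesterone-responsive genes were lower in 8 of 20 cases and higher in 3 (median -0.70, percentile 0.35), among them Il13ra2 (-3.72) and Lrp2 (-3.66, probes from -5.33 to -3.33). Uterine epithelial genes had a median of -0.47 (percentile 1.45), with 6 of 18 higher and 7 lower. Ovgp1 was at 0.44 by its brightest probe, but its probes ran from -2.99 to 0.44.

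The remaining lists lay inside the central 95% of random lists after vasectomized mating. The endothelial list stood at -0.59 (percentile 2.74), with Pecam1 at -2.30, mast cell and eosinophil genes at -0.66 (percentile 4.09), with the eosinophil receptor Ccr3 at 3.67 against the mast cell protease Cpa3 at -1.72, and steroid receptors and enzymes at -0.50 (percentile 4.21). Growth factors had a median of 0.47 (percentile 85.2), with Fgf2 at 4.21 and Tgfa at -2.76. Antigen presentation stood at 0.68 (percentile 94.0), with Cd40 at 3.04, B and plasma cells at 0.52 (percentile 74.0), with Ms4a1 at 2.37, and sperm and testis transcripts at 0.75 (percentile 88.4). Immediate early genes stood at 0.31 (percentile 48.7), with Junb at 3.24, prostaglandin genes at 0.05 (percentile 49.0), ion and water transport at 0.06 (percentile 22.5) and skeletal muscle and nerve transcripts at 0.39 (percentile 71.1). For the following lists the sign of the median differed with at least 1 other scaling or background correction, so no direction is given: stroma (0.06, percentile 10.4), smooth muscle (0.17, percentile 15.1), T and NK cells (-0.04, percentile 31.1), oviduct secretory epithelium (-0.20, percentile 4.97), epithelial junctions (0.40, percentile 73.4), oestrogen-responsive genes (0.24, percentile 37.6), heat shock (0.10, percentile 10.3), cell cycle (-0.05, percentile 32.4), adipocytes (-0.03, percentile 32.7), red blood cells (-0.30, percentile 12.2) and reference genes (0.04, percentile 5.27).

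In total, 4990 genes were at least 2-fold higher and 3193 at least 2-fold lower among 19312 compared, a share of 61.0% higher. That share was 77.1% with normexp background correction (5771 higher, 1717 lower) and 55.0% with quantile normalization. Ratios in this comparison also depended on expression level. Random lists had a median of 0.63 when matched to the reference genes and 0.05 when matched to the cytokines, against 0.20 and -0.14 after normal mating. The counts past 2-fold include this offset, whereas the list percentiles take it into account. Scaling to the spike-in probes gave 211 higher and 16515 lower. Every probe was at least 2-fold higher for 449 genes with several probes, and at least 2-fold lower for 414.

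The comparison of both matings asks what differs when sperm are present, but a ratio in it can come from either array. Among genes with several probes, the probes lay over 2-fold apart for 49.9% here, with r of 0.43 between the first 2 probes. Interferon-stimulated genes were higher after normal than after vasectomized mating for 9 of 24 genes and lower for 5 (median 0.77, percentile 99.93), with Oas3 at 4.16 (probes from 2.57 to 4.16), Oasl1 at 3.17 and Cxcl9 at -2.51. Inflammatory cytokines were lower for 9 of 21 genes and higher for 3 (median -0.89, percentile 2.27). Il6 was 16.8-fold lower, Csf2 10.0-fold lower and the receptor antagonist Il1rn 8.46-fold higher. Macrophage markers were lower in 10 of 16 cases and higher in 1 (median -1.29, percentile 0.15), with Adgre1 at -3.76 and Ccr2 at -2.57 against Cd68 at 2.48. Neutrophil markers lay within 2-fold in 12 of 17 cases, with a median of 0.54 (percentile 99.4) that was -0.23 with normexp background correction. Ovary and cumulus transcripts were lower in 10 of 13 cases (median -1.80, percentile 0.030), with Cyp11a1 at -4.82 and Hsd3b1 at -4.07. Stromal genes were lower in 12 of 19 and higher in 1 (median -1.55, percentile 0), among them periostin, Postn (7.99-fold lower), Hoxa10 (-2.94) and Hoxa11 (-2.78), and progesterone-responsive genes were lower in 10 of 20 and higher in 1 (median -1.05, percentile 0.48).

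For normal against vasectomized mating the uterine epithelial list had 10 of 18 genes higher and 1 lower (median 1.27, percentile 100), with the keratin Krt19 at 2.49. The oviduct secretory list had 8 of 15 higher and 1 lower (median 1.22, percentile 100), with Muc1 at 3.13 (probes from 3.13 to 4.42) and Pax8 at 2.84, and the junction list 11 of 22 higher and 3 lower (median 0.96, percentile 99.99), with plakoglobin, Jup, at 3.54. Ciliated genes stood at 0.48 (percentile 99.3), with 8 of 22 higher and 3 lower. Immediate early genes went both ways, 4 of 23 higher and 5 lower (median 0.45, percentile 99.5). Genes with the largest ratios were Ceacam1 (4.97, probes from 3.33 to 4.97), Ntn5 (4.31), Lad1 (4.07), the lipoxygenase Alox15 (4.07), the splicing factor Prpf19 (3.81), Pmepa1 (3.79), the major vault protein Mvp (3.69), Them5 (3.68) and A2ml1 (3.68). Lad1, Prpf19 and Mvp stood at -0.22, -0.01 and 0.10 after normal mating against not mated, and at -4.29, -3.82 and -3.58 after vasectomized mating. Ceacam1, Pmepa1 and A2ml1 were higher after normal mating than not mated (2.80, 2.29 and 3.25). The largest bounds were at least 10.7-fold for Cyp2e1, 9.21-fold for Ston2, 8.94-fold for Nxf1, 8.74-fold for Vps8 and 7.62-fold for Wif1. Lowest were Mela (-10.63), Slc4a7 (-6.44), the nuclear receptor Nr5a2 (-6.07), the melanocyte enzyme Dct (-5.64), Tmsb15a (-5.61), Tmem52b (-5.13) and the keratin Krt2 (-4.96). Col24a1 (-5.16) and Myo1e (-4.72) also met the rule, but their probes ran from -5.16 to -0.86 and from -4.72 to 1.92. Lower by at least 80.5-fold was Cst12, by at least 77.0-fold Ccdc83, by at least 54.7-fold Prss35 and by at least 45.4-fold Hao2.

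The other lists lay inside the central 95% of random lists when both matings were compared. The lowest among them were T and NK cells (-1.20, percentile 2.84), with Gzma at -2.58, mast cells and eosinophils (-1.18, percentile 5.73), with the eosinophil receptor Ccr3 at -4.34, complement (-0.78, percentile 5.51), smooth muscle (-0.77, percentile 16.6), with Lmod1 at -3.78, and sperm and testis transcripts (-0.58, percentile 38.5). The sperm median was positive with cyclic loess scaling. Prostaglandin genes stood at -0.56 (percentile 6.82), endothelial markers at -0.56 (percentile 12.2), growth factors at -0.52 (percentile 17.3), with Fgf2 at -4.71, seminal vesicle transcripts at -0.51 (percentile 44.3) and skeletal muscle and nerve transcripts at -0.50 (percentile 29.1). Antigen presentation stood at -0.49 (percentile 22), proteases at -0.47 (percentile 30.0), B and plasma cells at -0.45 (percentile 38.4) and NF-kB genes at -0.42 (percentile 22.3), with Tlr7, a sensor of viral RNA, at -2.82. Secreted defence genes stood at -0.24 (percentile 64.3), a sign that differed with quantile and cyclic loess scaling, although Lcn2 was 7.61-fold higher. Medians near 0 were those of hypoxia (-0.03, percentile 78.5), reference genes (0.04, percentile 93.4), cell cycle (0.04, percentile 76.9), oestrogen-responsive genes (0.05, percentile 85.9), steroid receptors and enzymes (0.13, percentile 78.2), adipocytes (0.16, percentile 83.4), red blood cells (0.16, percentile 85.7), heat shock (0.21, percentile 95.8) and ion transport (0.23, percentile 97.2).

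In total, 2792 genes were at least 2-fold higher and 5310 lower among 18990 compared (34.5% higher), against 15397 and 250 with scaling to the spike-in probes. Random lists had a median of -0.45 here when matched to the reference genes and -0.25 when matched to the cytokines, and these counts include that offset. Every probe was at least 2-fold the same way for 409 higher and 515 lower genes with several probes.

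**Figure D3:**
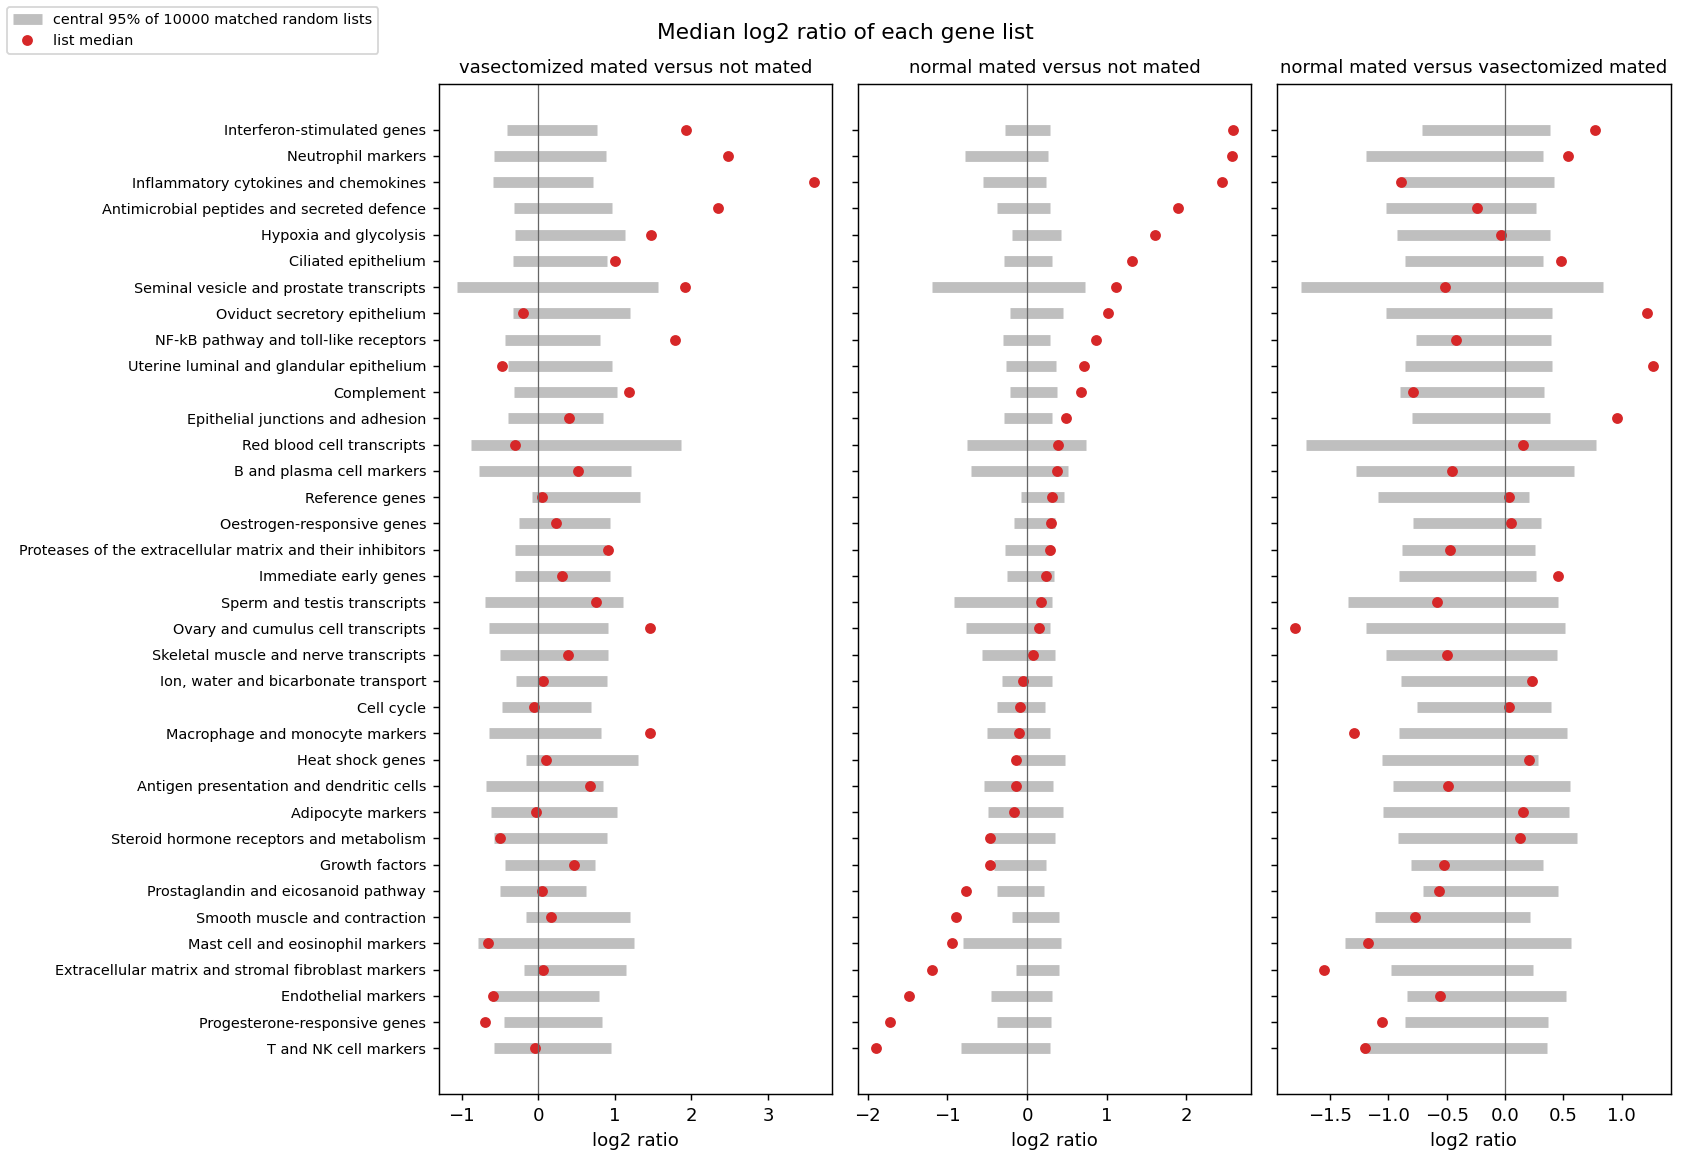
Median log2 ratio of each gene list (points, horizontal axis) in the 3 comparisons, beside the central 95% of 10000 random lists matched on expression (grey bars). In normal mated versus not mated, the interferon-stimulated genes lie highest at 2.59 and the T and NK cell markers lowest at -1.90.

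Genes shared by both matings were counted as at least 2-fold the same way against the not mated array and within 1.5-fold of each other: 492 were higher and 593 lower. With 1 array per group, this pattern cannot be told apart from the not mated array alone standing apart. In this and the following patterns, 2 arrays that gave no ratio for lack of signal over background were taken as within 1.5-fold. With only genes well above background on both arrays, 381 were lower after both matings. Genes apart on the normal-mated array alone numbered 336 higher and 570 lower, and those apart on the vasectomized-mated array alone 2457 higher and 1344 lower. Across 17206 genes, r between the log2 ratios of the 2 matings was 0.47 and their covariance 0.574, where simulated unchanged arrays sharing the not mated array gave 0.43 and 0.00561. The 2 matings had 1073 higher genes in common, against 444.5 for independent lists and 0 in the simulation, and 907 lower genes, against 429.9 and 0. These overlaps count 18706 genes compared in both, with 4596 and 1809 higher and 3190 and 2521 lower after vasectomized and normal mating. Part of this excess may come from the shared not mated array, which cannot be split and which the figures for independent lists leave out. The simulation held replicate-spot noise only, so its overlaps of 0 were fixed by that small noise.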

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

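All tests in this part were chosen after the results were seen. The E1A spike-in probes, which detect transcripts added in the laboratory and are used in no comparison under the main scaling, differed between arrays. Their mean log2 signal before scaling was 1.13 higher on the vasectomized-mated than on the not mated array, and 0.22 higher on the normal-mated than on the not mated array. The 75th percentile of the other signals differed the opposite way, at 295 and 708 against 874 on the not mated array. Relative to that percentile the spike-ins therefore stood further apart. Scaling to them moved the median of all genes by -2.77 (vasectomized mated versus not mated) and -0.54 (normal mated versus not mated). The amounts added are not given in the sources used here. The slope of the spike-in signals was 0.912, 0.838 and 0.915 on the not mated, vasectomized-mated and normal-mated arrays, and the software put only the vasectomized-mated one outside its accepted range.

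The same array was the one on which probes of a gene lay apart. Noise of dim spots is argued against, because 40.7% of 1932 genes in the brightest part of the range had probes over 2-fold apart, against 4.81% for normal mated versus not mated. The signals had already been corrected for spatial trends, so r of 0.0125 between neighbouring spots argues only against uneven hybridisation left after that correction. Unevenness before the correction was not tested. Transcript forms shared by both matings are argued against by the 15.5% of 3003 genes with probes apart after vasectomized mating that also had probes apart after normal mating. Loss of the 5' ends of the RNA as the whole cause is argued against by the 39.0% of 2451 genes with end probes over 2-fold apart whose 5'-most probe was the higher one, but as part of the cause it stays open, since the 3'-most probe was higher for 59.0% of 5092 genes with a median excess of 0.29 on the log2 scale, against 50.7% and 0.01 for normal mated versus not mated. Across all genes this excess did not grow with the genomic distance of the probes (Spearman rho -0.0789 for pairs up to 3000 nt apart and -0.137 for all pairs), which spans introns and so decides nothing, and labelling or hybridisation of that sample and transcript forms present after vasectomized mating alone were not tested.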

How the results depend on the processing

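The settings named here as scaling to spike-in probes, the 3'-most probe and the comparison without the vasectomized-mated array were chosen after seeing the data, and the other settings before. No paired analysis was possible because each group has 1 array. Each count of genes and of patterns stayed within 1.5 times its main value with quantile normalization, the median of detected probes, cyclic loess, flagged spots kept, the median over probes and the 3'-most probe. Without the vasectomized-mated array, 1896 genes were at least 2-fold higher and 2548 lower for normal mated versus not mated. The median of all genes moved by -0.12 (vasectomized mated versus not mated) and 0.18 (normal versus vasectomized mated) with quantile normalization, by 0.10 in the first with the median of detected probes, by 0.19 in the last with cyclic loess, by 0.31 and -0.22 with normexp, and by -2.77, 2.17 and, for normal mated versus not mated, -0.54 with spike-in scaling.

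With normexp background correction 1717 genes were lower after vasectomized mating, 2300 differed after normal mating with 933 of them lower, and 1702 were higher after normal than vasectomized mating. The patterns under it were 206 higher and 247 lower after normal mating alone, 198 lower after both and 789 lower after vasectomized mating alone. Spike-in scaling gave 16726 (211 higher, 16515 lower), 1033 higher and 5517 lower, and 15647 (15397 higher, 250 lower) for vasectomized mated versus not mated, normal mated versus not mated and normal versus vasectomized mated. This scaling moves every gene of an array by 1 amount.

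At 1.5-fold, 12308 genes (5049 lower) differed after vasectomized mating, 8154 (3374 higher, 4780 lower) after normal mating, and 4504 were higher in normal versus vasectomized mated. At 3-fold the counts were 4213 (2715 higher, 1498 lower), 1929 (973 higher, 956 lower) and 3916 (1233 higher, 2683 lower). The patterns at 1.5-fold were 916 higher and 1264 lower after both matings, 746 and 1291 after normal mating alone, and 3869 and 2258 after vasectomized mating alone. At 3-fold they were 220 and 206, 125 and 134, and 1100 and 524. The threshold itself accounts for these differences.

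Without a filter on dim probes, 14396 genes differed between the matings (11120 lower), and 979 were lower after normal mating alone. With only genes well above background on both arrays, 381 were lower after both matings. The correlation of the matings was 0.492 with quantile normalization and 0.486 with the median over probes.

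Of the list medians outside the central 95% of random lists, that of the seminal vesicle list for normal mated versus not mated was -0.34 with only genes well above background on both arrays and -0.69 without the filter, and that of neutrophil markers for normal versus vasectomized mated was -0.23 with normexp. Of the lists inside the central 95%, the sign of the median differed with at least 1 setting for 12 lists in vasectomized mated versus not mated, 5 in normal mated versus not mated and 10 in normal versus vasectomized mated. Among single genes, for vasectomized mated versus not mated, the opposite sign to the main value was found for Ceacam10 (0.35) and Prf1 (0.24) with normexp, Cdh5 (-0.11) and Esr1 (-0.67) with the median over probes and Dnaja1 (0.10) with the 3'-most probe. For normal versus vasectomized mated it was found for Tgfa (-0.21) with normexp, B2m with the median over probes and with the 3'-most probe (-0.096 in each), and Dnaja1 (-0.26) and Myo1e (1.92) with the 3'-most probe. For normal mated versus not mated no named gene at least 2-fold apart had the opposite sign, among 1403 alternative values of 157 named genes. The sizes also depended on the processing. The log2 ratios of named genes moved by more than the replicate-spot noise in 418 cases with normexp (57 did not), in 291 with cyclic loess (187 did not), in 272 with quantile normalization (206 did not) and in 177 with the median of detected probes (301 did not). List medians moved by more than 1 SD of their random lists in 25 cases with normexp, 25 with cyclic loess and 28 with quantile normalization among 108. Apart from the thresholds and the uniform spike-in shift, the cause was not tested. Signal over background limits genes near the floor, and only those not well above background on 1 array are given as bounds. Genes dim on the not mated array but above that limit have exact ratios that are limited too. Examples are Chil1 (log2 level -5.83 on the not mated array) and Sprr2d (-5.37).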

Other observations

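All tests in this part were chosen after the results were seen, and so were the gene families and single genes described. The Sprr2 genes, small proline-rich proteins of stratified and uterine epithelium, had a median log2 ratio of 5.60 over 8 measured genes after normal mating and 3.82 after vasectomized mating against not mated, and of 2.00 between the matings. Cross-hybridisation between these similar genes was not tested, so they are not 8 separate measurements for certain, and the probes of Sprr2a1 ran from 0.18 to 9.13 after normal mating. Granzymes, the proteases of cytotoxic lymphocytes, had a median of -2.75 after normal mating with 6 of 7 at least 2-fold lower, and -0.71 after vasectomized mating (percentile 5.23). With normexp background correction these medians were -1.24 and 0.16. Killer cell lectin-like receptors, found on NK cells, had a median of -1.20 after normal mating with 11 of 20 lower, but 1.60 after vasectomized mating with 17 of 23 higher, and with normexp background correction the medians were -0.19 and 1.43. Cross-hybridisation between these receptors was not tested either. After vasectomized mating Klrb1c (-0.08) and Klrg1 (-0.30) were within 2-fold, and the T and NK cell list had a median of -0.04. Posterior Hox genes (groups 9 to 13) had a median of -2.09 after normal mating with 6 of 9 lower, and -0.74 after vasectomized mating (percentile 4.9). With normexp background correction these medians were -1.20 and 0.09. Anterior Hox genes had a median of -0.19 after normal mating with 16 of 21 within 2-fold. Cytosolic ribosomal protein genes had a median of 1.42 on the vasectomized-mated array with 57 of 83 at least 2-fold higher than on the not mated array. Random lists matched on expression had a median of 0.89 in that comparison. The ribosomal protein genes had a median of only 0.06 with quantile normalization and 0.26 with cyclic loess. After normal mating their median was 0.20, with 81 of 83 within 2-fold, and -0.15 with quantile normalization and -0.23 with cyclic loess.

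The single genes that follow were picked for their large ratios on the vasectomized-mated against the not mated array and were not tested as a group. Mrap, an accessory protein of the corticotropin receptor, was 77.8-fold higher, H1f8, the linker histone of oocytes, 39.0-fold, Nr5a2 27.2-fold, Agrp 38.8-fold and Ghrh, growth hormone-releasing hormone, 60.5-fold. After normal mating the values against not mated were 4.76-fold higher for Mrap, 4.52-fold for Agrp and 24.9-fold for Ghrh. H1f8 was also higher after normal mating, with a log2 ratio of 3.40, and Nr5a2 was lower (-1.31).

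Ovary and cumulus transcripts were higher on the vasectomized-mated array. Random scatter between probes stays open, because the percentile of 99.93 among matched random lists is what drew attention to this list among 108 list comparisons. Ovary or cumulus cells in that pool may also be involved, since 57.1% of 14 measured members were at least 2-fold higher, which is too few to settle it and too many to exclude it. The largest ratios in the list were those of Hsd3b1 (8.11) and Cyp11a1 (at least 7.20), which other steroid-making cells also express. Both were also higher after normal mating than not mated (4.04 and at least 2.38). For normal mated versus not mated, 5 of 14 list members were at least 2-fold higher and 2 lower (median 0.15). The oocyte transcripts Gdf9 (3.64), Oosp1 (at least 6.01) and H1f8 (5.29) were higher on the vasectomized-mated than on the not mated array. After normal mating they stood at 1.97, at least 3.61 and 3.40 against not mated. They were put together after their values were seen, so they leave ovary or oocyte material in the pool open. Whether mating with a vasectomized male has a part in it was not tested, because that group has 1 array.

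Stromal, muscle and endothelial markers were lower and ciliated and oviduct secretory markers higher on the normal-mated than on the not mated array. Dilution by incoming leukocytes as the only cause would have lowered ciliated epithelium too, which had a median of 1.32. That rise is part of the pattern described, so dilution beside another cause stays open. A smaller share of non-epithelial tissue, which would lower the 3 lists alike, could not be settled, because their medians lay 0.583 apart, further than in 95% of shuffles of their genes (0.530), but 0.253 apart with cyclic loess and 0.327 with quantile normalization. A smaller uterine part of the dissected tissue stays open too, because the uterine epithelial list ran from -0.52 to 1.83 between its quartiles. The posterior Hox genes (median -2.09) and the uterine gland proteases Prss28 (-9.26) and Prss29 (-4.55) were lower, but by unlike amounts. After vasectomized mating Prss28 (at least 2833-fold) and Prss29 (-6.05) were lower as well, with the posterior Hox median at -0.74, so their low values decide nothing here. Regulation of any of these genes by mating, which the design names, remains open and untested. With 1 pool per group it cannot be told apart from any other difference between the pools, which holds for all results above.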
